A study of Mus musculus with 9 samples.

How the data were processed

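Total RNA from the brainstem of male Chat-Cre:Ai9 mice was profiled in 3 regions named dorsal, ventral and target, with 3 arrays each. Per the labels' protocols, tissue was lysed in QIAzol, RNA was purified with the miRNeasy Micro kit, and biotin-labelled cRNA was made with the Illumina TotalPrep kit. The arrays were Illumina mouse whole-genome BeadChips of 45281 probes, each read through many copies of 1 bead type (a median of 43 to 45 beads per probe). How the tissue was dissected and what set the target region apart are not given in the sources used here.

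Per the file headers, the authors exported bead intensities with GenomeStudio 1.6.0 on a linear scale, once with no normalization and once after quantile normalization between arrays, and nothing was averaged over arrays. Per the file headers the same export holds a detection score for each probe on each array, which compares it with the negative control beads of that array; the values rose to 1 for bright probes, so 1 minus the score was used as the detection p. The deposited export also gives the other measure used here, the number of beads behind each intensity. A further deposited table of intensities was equal to the unnormalized one (largest difference 0), and the values of the series matrix were equal to the quantile-normalized intensities (largest difference 0), linear and not centred, with column medians from 182.3 to 182.5 and a lowest value of 95.6. The unnormalized medians ran from 146.1 to 230.9. No column of values lacked a sample, and no pair of arrays held identical values.

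All log2 values were computed here from the intensities the authors deposited. In R 4.3.3 with limma 3.58.1, neqc corrected the background by the normexp model, with negative controls inferred from the detection p, added an offset of 16, quantile-normalized the arrays and took log2. A probe was tested when its detection p was below 0.05 on at least 3 of the 9 arrays, which left 20461 probes. Probe names are those of the array, updated where the RefSeq gene table of mouse assembly GRCm38.p6 allowed: 27760 probes matched a symbol, 8035 a synonym, and 9486 kept the array's own name. Of the tested probes these were 13510, 3761 and 3190. No probe sequences or coordinates were used. For a gene with several tested probes the one with the highest mean level stands for the gene, and other probes are reported where they differ. Shares of second probes, and means and counts over several probes outside the gene lists, take probes that share a name on the array before it was updated. A region with no array above background has only a bound: the bright region's mean is set against, on each array, the higher of the probe's own level and the lowest level among probes above background.

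Probes were tested with lmFit and eBayes in 1 fit of all 9 arrays with the region as the only term, since the 3 regions then share 1 estimate of the spread. Contrasts were target minus dorsal, target minus ventral, dorsal minus ventral and target minus the mean of the other two. Probes higher or lower in target than in each neighbour were those passing in both of its pairwise contrasts. P-values were adjusted by Benjamini-Hochberg over the probes tested in a contrast, and 0.05 was the limit. Means of a few genes were compared by exact permutation of the arrays of both regions, without regard to the mouse. Gene lists were tested with camera at a preset correlation of 0.01, on 1 probe per gene, for lists with at least 4 measured genes, and adjusted over the lists.

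The 32 lists were neuropeptides; neuropeptide and orexin receptors; monoamine, acetylcholine and adenosine receptors; cholinergic, cranial motor, serotonergic, noradrenergic, dopaminergic, GABAergic, glycinergic and glutamatergic neurons; GABA-A and glycine receptor subunits, ionotropic glutamate receptors, potassium and HCN channels and calcium-binding proteins. They went on with transcription factors of the midbrain tectum and tegmentum, hindbrain Hox genes, cerebellar neurons, cortical and hippocampal neurons, and thalamus, habenula and pretectum. The rest were pan-neuronal genes, myelin and oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia, endothelial cells, mural and meningeal cells, ependymal and choroid plexus cells, blood cells, immediate early genes, heat shock and hypoxia response, and circadian clock genes. Named genes were, for each pair of regions, the 10 largest called differences in each direction (or all that passed, if fewer; clone-named and predicted loci left out), the genes higher or lower in target than in each neighbour, up to 4 called members of each list per contrast, up to 2 members with the largest difference for a list with no called member, and 27 genes named whatever their values. Any other gene named was chosen after its values were seen, and a few genes that the rule takes are not reported here. The lists, the rule, the contrasts, the tests and all alternatives except those said to be added later were fixed before the data were examined.

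Column names of a deposited table mark arrays of the same number as coming from the same mouse, so the numbers pair the arrays. Deviations from the region means correlated between -0.0963 and 0.146 for arrays of the same mouse and between -0.160 and 0.215 for arrays of different mice. The fit without the mouse had been fixed as the one to report because the sample labels do not state the pairing, and the fit with the mouse as a block is given beside it where it changes a call. P-values of the fit without the mouse measure the spread between the 3 arrays of a region, pooled over the regions. Only the fit with the block measures how the differences between regions vary between the 3 mice.

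The alternatives were no background correction (raw intensities floored at 1), an offset of 50, the authors' quantile-normalized table and series matrix (floored at 16), median centring in place of quantile scaling, no detection filter, a detection p below 0.01 on all 9 arrays, the mouse as a fixed or random block, trended and robust moderation, array weights, a fit of only the regions compared, and each array left out in turn. For lists they also included an estimated correlation, fry, and the mean of a gene's probes. Means over the probes of an array name, and counts of names with more than 1 called probe, were added after the data were seen. A block for the BeadChip was planned and not run, since chip identifiers are not given in the sources used here.

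The fit was tested on simulated data for 20461 probes with 200 changed, 100 by 2-fold and 100 by 4-fold. Of the 2-fold changes 31, 24 and 21 were called for target against dorsal, target against ventral and dorsal against ventral, and of the 4-fold changes 66, 74 and 68, each in the right direction, with 5, 2 and 3 false calls. The list test was run 10 times for target against dorsal on 14313 genes with 1 list shifted by 0.5. The shifted list was called in 9 runs for noradrenergic neurons, 10 for astrocytes and 10 for potassium and HCN channels. False calls among unshifted lists were 0 of 270, 1 of 300 and 0 of 310. The simulated genes varied independently, so these rates do not carry over to lists whose genes vary together. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.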

Results

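Gene expression was measured in 3 regions of the mouse brainstem, which the labels call dorsal, ventral and target, with 3 arrays per region and 9 in all. The tissue came from male mice aged 8 weeks that carried Cre recombinase under Chat, the gene of the acetylcholine-synthesizing enzyme, together with Ai9, a reporter that makes the red protein tdTomato where Cre is active. The labels say neither what the target region was nor how the tissue was taken. Each array holds 45281 probes, and 16703 (ventral array 2) to 19945 (dorsal array 3) of them were above background. A total of 20461 probes with 14313 gene names were tested. Pairs of arrays correlated between 0.892 and 0.961 over the tested probes, with a median of 0.944 within a region and 0.923 between regions. The number of arrays limits the precision of every value below. Levels and differences are on the log2 scale, with n = 3 arrays per region, and arrays of different regions that carry the same number came from the same mouse. Where a region lay at background on all 3 of its arrays, the fold is given as a bound.

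Neurotensin neurons are named in the title of the series, so Nts, which encodes the neurotensin precursor, was examined first. Nts was high in target and dorsal and low in ventral. Its brighter probe (7320255) read 9.87 ± 0.09 (SD, n = 3) in target, 9.26 ± 0.03 in dorsal and 6.42 ± 0.48 in ventral, where 2 of 3 arrays were above background. The level in target was 10.9-fold that in ventral (log2 difference 3.45, SE 0.23, limma adjusted p = 2.27e-04), and the level in dorsal was 7.18-fold that in ventral (2.84, SE 0.23, adjusted p = 4.03e-04). The target level exceeded the dorsal level by 0.61 (SE 0.23), which did not pass the test (adjusted p = 0.457). The dimmer Nts probe (1850095) gave at least 5.23-fold more in target than in ventral (adjusted p = 1.15e-04), at least 2.96-fold more in dorsal than in ventral (adjusted p = 2.97e-04), and 0.82 more in target than in dorsal (adjusted p = 0.146). Neither neurotensin receptor gene passed in any pair, where the largest difference was 0.51 for Ntsr1, dorsal over ventral (adjusted p = 0.357, with 2 of 3 ventral arrays above background), and 0.19 for Ntsr2, dorsal over ventral (adjusted p = 0.587). Whether Nts was chosen for study from these same arrays is not given in the sources used here, and in that case its difference is not independent evidence.

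**Figure D1:**
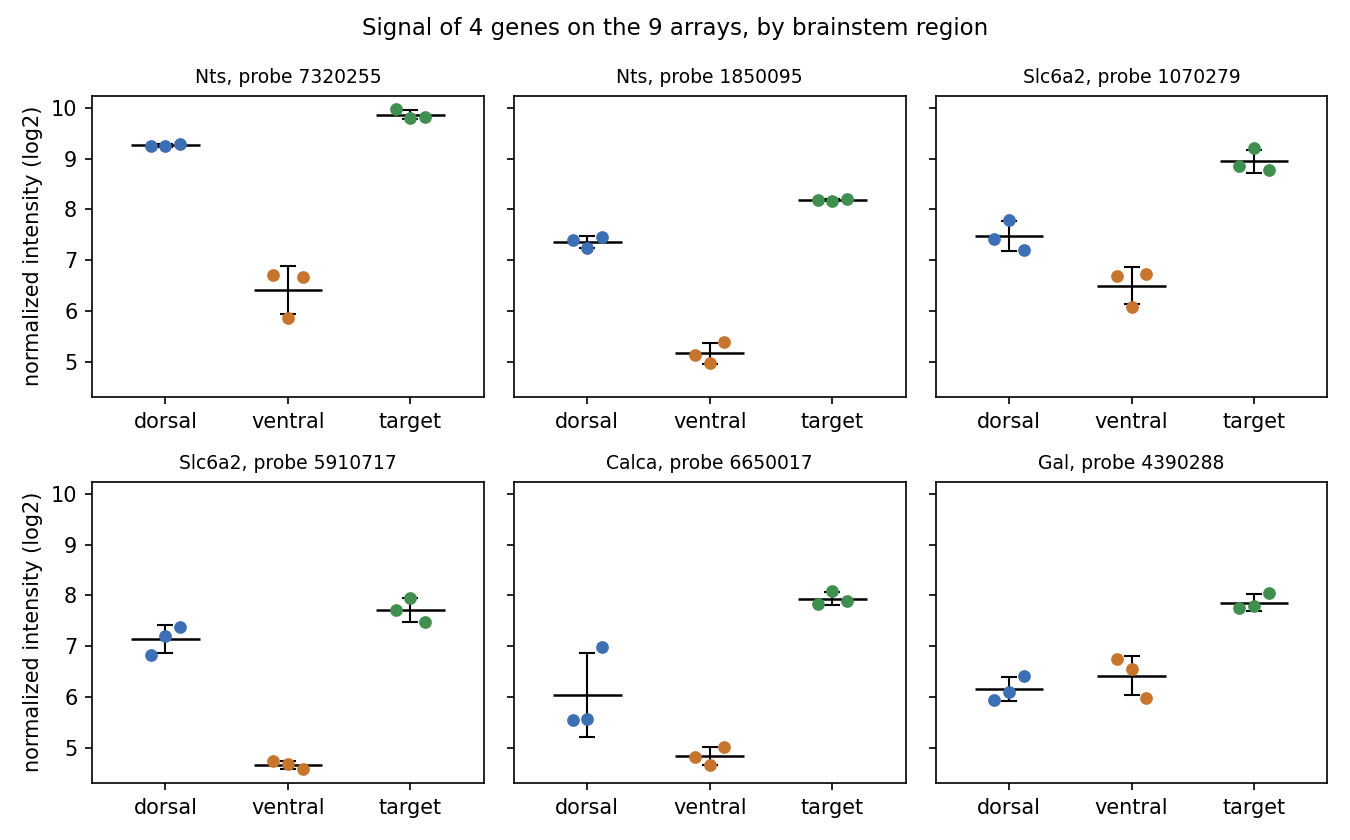
Normalized intensity (log2, vertical axis) of 6 probes of Nts, Slc6a2, Calca and Gal on the 9 arrays, by region (horizontal axis); each dot is 1 array, the long bar is the mean and the error bar the SD over 3 arrays. The mean of the brighter Nts probe was 9.87 in target, 9.26 in dorsal and 6.42 in ventral, and the Gal mean was 7.86 in target, 6.15 in dorsal and 6.43 in ventral.

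Among the other genes named whatever their values, 11 genes of transmitters and of other cell traits passed in no pair and are given next. Slc6a5, Calca and Mbp did pass in a pair and are given with that pair below. The largest pairwise difference of the brightest probe was 0.22 for the vesicular glutamate transporter gene Slc17a6 (target over ventral, adjusted p = 0.538). It was -0.09 for Gad1 (target minus ventral, adjusted p = 0.837) and 0.14 for Gad2 (target over ventral, adjusted p = 0.742), which both encode GABA-synthesizing enzymes, and -0.31 for the vesicular GABA transporter gene Slc32a1 (target minus ventral, adjusted p = 0.451). It was -0.11 for Tph2, the serotonin-synthesizing enzyme of neurons (dorsal minus ventral, adjusted p = 0.865). For peptide genes it was -0.36 for Tac1 (dorsal minus ventral, adjusted p = 0.690), -0.18 for Penk (dorsal minus ventral, adjusted p = 0.839) and -0.23 for Crh (dorsal minus ventral, adjusted p = 0.794). The rest gave -0.12 for Pvalb (target minus dorsal, adjusted p = 0.871), 0.25 for Gfap (dorsal over ventral, adjusted p = 0.460) and 0.77 for Hoxb2 (target over dorsal, adjusted p = 0.631). Not all arrays were above background for Tph2 (1 of 3 in dorsal and in ventral), Tac1 (2 of 3 in ventral), Crh (2 of 3 in dorsal and in ventral) and Hoxb2 (1 of 3 in dorsal, 2 of 3 in target). Of the 27 genes to be named whatever their values, 10 had no probe above background on enough arrays to be tested: Chat, Slc18a3, Th, Dbh, Slc6a3, Cck, Pax7, Gabra6, Neurod6 and Fos. The 3 Chat probes exceeded background on 1, 2 and 0 of the 9 arrays.

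The first comparison asked which genes differed between target and dorsal. Cdkn2d, which encodes an inhibitor of cyclin-dependent kinases, was higher in target than in dorsal by 3.24 (SE 0.21, n = 3, adjusted p = 0.00122), at means of 9.10 and 5.86. Coasy, the coenzyme A synthase gene, was higher in target by 1.69 (SE 0.21, adjusted p = 0.0435), and Ppdpf was at least 2.49-fold lower in target (adjusted p = 0.0364). With the mouse as a block the adjusted p was 0.00718 for Cdkn2d, 0.0984 for Coasy and 0.166 for Ppdpf, so that only the first of these 3 calls was kept. Leaving out any 1 of the 9 arrays ended the other two calls as well (adjusted p from 0.0670 to 0.145 for both genes). In all, 12 probes passed, 9 higher and 3 lower in target, and 1965 had an unadjusted p below 0.05. The block left 3 calls, 2 of them shared with the 12. Adssl1, an adenylosuccinate synthase gene singled out after its values were seen, is the other shared call, at 2.70 (SE 0.23, adjusted p = 0.00652, 0.0119 with the block, with 1 of 3 dorsal arrays above background). For 11 of the 12 probes the target mean lay between the dorsal and ventral means, and the same 11 also passed between dorsal and ventral.

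Of the 32 gene lists fixed in advance, only that of noradrenergic neurons was shifted between target and dorsal by camera, limma's test of a list against all other genes (adjusted p = 0.00819, higher in target, but 0.299 with an estimated correlation, a form in which no list passed in any comparison). The mean of its 7 measured genes was 0.64, and 6 of the 7 had a positive difference. None of the 7 passed over all probes, and 2 did when adjusted over the list alone. With the mouse as a block the list's adjusted p was 0.0248. Its largest members were Gal, the galanin gene, at 1.71 (SE 0.23, adjusted p = 0.0506), and Slc6a2, the noradrenaline transporter gene, at 1.47 (SE 0.25, adjusted p = 0.0772; probe 5910717 gave 0.57, adjusted p = 0.422). The other 5 averaged 0.26 (exact permutation p = 0.2 on both sides with the mouse ignored, where 3 against 3 unpaired arrays cannot go below 0.1). Slc6a2 and Gal passed against dorsal without background correction, at 0.97 (adjusted p = 0.00978, from 0.00978 to 0.245 over all alternatives) and 0.80 (adjusted p = 0.0145, from 0.0144 to 0.184 over all alternatives). Calca, the gene of calcitonin and CGRP, was 1.90 higher in target than in dorsal (SE 0.36, adjusted p = 0.102), where 1 of 3 dorsal arrays was above background. Without that array, dorsal array 3, the call passed (adjusted p = 0.0168, from 0.0168 to 0.308 over all alternatives), and no size is given since both remaining dorsal arrays were at background. It belongs to the lists of neuropeptides and cranial motor neurons. The neuropeptides averaged 0.31, with 9 of 14 positive, 0 passing over all probes and 2 adjusted over the list alone (camera adjusted p = 0.195). The motor neuron genes averaged 0.63, with 5 of 6 positive, 0 passing and 1 adjusted over the list alone (camera adjusted p = 0.142). Both lists passed without dorsal array 3 (adjusted p = 0.0390 for each). No member of any list passed over all probes between target and dorsal. By fry, limma's rotation test of whether a list moves one way, the midbrain transcription factors passed beside the noradrenergic list (adjusted p = 0.0273, 4 of 15 adjusted over the list alone), while camera gave them 0.524. Their largest value was at least 1.70-fold for Barhl1 (adjusted p = 0.371).

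The count of 12 fell to 1 without target array 3, 3 without dorsal array 2, 4 without dorsal array 3 and 2 without any single 1 of the other 6 arrays. It was 88 without background correction (68 higher, 20 lower), and with arrays centred on their medians in place of quantile scaling it was 17, of which 3 were higher and 14 lower in target.

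Target and ventral differed much more. Beside Nts, Mmel1, which encodes a membrane metalloendopeptidase related to neprilysin, was at least 26.1-fold higher in target (n = 3, adjusted p = 1.15e-04). Slc6a2 was 2.45 higher (SE 0.25, adjusted p = 0.00227), and its dimmer probe gave at least 3.76-fold (adjusted p = 2.08e-04). Calca was at least 4.40-fold higher by probe 6650017 (adjusted p = 0.00499). Its probes 6760270, 6580452 and 1470465 were above background on 0 of the 9 arrays, target included, and were not tested. Gal was 1.44 higher (SE 0.23, adjusted p = 0.0234, and 0.0674 with the mouse as a block). The Gal call was also lost without ventral array 2 (0.0554), target array 1 (0.0683), target array 2 (0.0726) or target array 3 (0.104). In the other direction Cops6, a subunit gene of the COP9 signalosome, was at least 16.2-fold lower in target (adjusted p = 1.91e-05). The other genes among the 10 largest that were higher in target were the olfactory receptor gene Olfr711 (at least 6.91-fold), the microtubule-affinity kinase gene Mark4 (3.59, SE 0.34, with 1 of 3 ventral arrays above background) and the Rab GTPase-activating protein gene Tbc1d15 (3.41, SE 0.44, with 2 of 3). They went on with Arhgap27 (at least 3.77-fold), the SAGA complex gene Supt20 (2.81, SE 0.29), the cell adhesion gene Sdk2 (at least 3.45-fold) and Dipk1b (at least 3.10-fold). The other 9 that were lower in target were Gab1, an adaptor of receptor tyrosine kinases (-2.70, SE 0.32, with 2 of 3 target arrays above background), Tesk1 (-2.65, SE 0.38), the sodium pump subunit gene Atp1b2 (-2.32, SE 0.26) and Rogdi (-2.19, SE 0.33, with 2 of 3). The rest were the nucleotide-sugar transporter gene Slc35b4 (-2.09, SE 0.40, with 1 of 3), Tagln3 (-1.94, SE 0.34), the mitochondrial ribosome gene Mrps34 (-1.90, SE 0.29), Frmpd4 (at least 2.51-fold) and the mitochondrial sodium-calcium exchanger gene Slc8b1 (at least 2.55-fold). Adjusted p-values of these 20 genes ranged up to 0.0414, and all 20 calls held with the mouse as a block. Of the 20, 3 had another tested probe: it was also called in the same direction for Nts, pointed the same way without passing for Dipk1b and pointed the opposite way for Sdk2. The rest, Cops6, Mmel1 and Olfr711 among them, had 1 tested probe each. No second probe checked these calls as differences of the gene.

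Over all probes 365 passed between target and ventral, 239 higher and 126 lower in target, with a median size of 1.36 and 69 of over 4-fold; 67 of the 365 had a region at background on all 3 arrays. At an unadjusted p below 0.05 there were 3271. With the mouse as a block 154 passed, 106 higher and 48 lower, of which 145 were among the 365. The share of higher calls moved with the processing: without background correction 431 were higher and 402 lower, and 431 and 401 in the table the authors had quantile-normalized. Median centring in place of quantile scaling gave 134 higher and 44 lower. Leaving out 1 array gave 183 calls without dorsal array 2, 178 without dorsal array 3, 121, 163 and 186 without ventral arrays 1, 2 and 3, and 116, 92 and 64 without target arrays 1, 2 and 3. Of 160 genes with a called probe and another tested probe of the same array name, the other probe pointed the same way in 85 (53.1%, exact binomial 95% interval 45.1 to 61.0%).

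Several gene groups held called members between target and ventral, and no list passed by camera (3 had an unadjusted p below 0.05; 0 passed with an estimated correlation, and 3 by fry). Among neuropeptides 3 of 14 measured genes were higher, Nts, Calca and Gal, none was lower and 11 did not pass, with 4 passing when adjusted over the list alone (camera adjusted p = 0.640). Of 7 noradrenergic genes 2 were higher, Slc6a2 and Gal, and 5 did not pass, with 2 adjusted over the list alone (mean 0.66, camera adjusted p = 0.119, fry 0.00810). Calca was the 1 of 6 cranial motor neuron genes that was higher, with 2 adjusted over the list alone (mean 0.86, all 6 positive, camera adjusted p = 0.119, fry 0.0410). Blood cell genes had 0 of 6 passing and 2 adjusted over the list alone, with all 6 positive and a mean of 0.60 (camera adjusted p = 0.0806, fry 0.0410). Their largest values were 1.05 for Bpgm (adjusted p = 0.329, with 2 of 3 ventral arrays above background) and 0.70 for the globin gene Hba-a1 (adjusted p = 0.125). Single members were higher in target in other lists: Prima1, the anchor of acetylcholinesterase, among 4 cholinergic genes (1.36, adjusted p = 0.0303, 0.0708 with the block), and the kainate receptor subunit gene Grik4 among 13 ionotropic glutamate receptors (1.16, adjusted p = 0.0471, 0.0799 with the block, with 2 of 3 ventral arrays above background). The next was the transcription factor gene Nkx2-2 among 15 midbrain transcription factors (1.31, adjusted p = 0.0412, 0.0911 with the block). It was followed by the sialidase gene Neu4 among 12 oligodendrocyte precursor genes (2.01, adjusted p = 9.26e-04, but 1.04 averaged over 2 probes). Also higher was Slc13a4 among 15 mural and meningeal genes (2.28, adjusted p = 0.0168, with 1 of 3 ventral arrays above background). So was the oxygen-sensing hydroxylase gene Egln3 among 20 heat shock and hypoxia genes (2.31, adjusted p = 0.0385, 0.0641 with the block, but 1.25 averaged over 2 probes). The clock gene Per2 was higher among 12 circadian genes (1.32, adjusted p = 0.0488, 0.0708 with the block). Laptm5, a lysosomal gene of microglia and other leukocytes, was lower in target and the only called gene of 15 microglial ones (-1.63, adjusted p = 0.0356, 0.0610 with the block). Adjusted over each list alone, these counts were 1, 2, 2, 2, 1, 1, 2 and 1 in the order named, and the camera adjusted p was 0.812, 0.812, 0.902, 0.879, 0.812, 0.812, 0.812 and 0.941.

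Dorsal and ventral were the most different pair. Nts was 2.84 higher in dorsal, and Mmel1 at least 12.2-fold higher (n = 3, adjusted p = 2.48e-04). Cops6 was at least 17.2-fold lower in dorsal (adjusted p = 9.60e-06). Also lower were Cdkn2d (-4.36, SE 0.21, adjusted p = 2.44e-05) and the actin-regulating kinase gene Tesk1 (-4.26, SE 0.38, adjusted p = 5.41e-04, with 1 of 3 dorsal arrays above background). Among the 10 largest that were higher in dorsal were also the olfactory receptor genes Olfr711 (at least 8.82-fold), Olfr214 (at least 4.16-fold) and Olfr10 (at least 5.40-fold) and Tbc1d15 (3.84, SE 0.44, with 2 of 3 ventral arrays above background). The rest were Dipk1b (at least 6.66-fold), the arylamine acetyltransferase gene Nat2 (3.26, SE 0.25, with 1 of 3), Morn1 (at least 4.93-fold) and the hair cell gene Clrn1 (at least 3.41-fold). The other 7 that were lower were Gab1 (at least 7.26-fold), Erbin, which binds the receptor ErbB2 (-3.44, SE 0.35, with 2 of 3 dorsal arrays above background), Atp1b2 (-3.34, SE 0.26) and Fam120a (-3.04, SE 0.29). The rest were Lrig1, a negative regulator of EGF receptors (-3.03, SE 0.30, with 2 of 3), the nucleotide kinase gene Cmpk2 (-2.85, SE 0.28, with 2 of 3) and the ATP synthase assembly gene Atpaf2 (-2.70, SE 0.26). Adjusted p-values of these 20 genes ranged up to 0.00316, and all 20 calls held with the mouse as a block. Of the 20, 6 had another tested probe, which was also called in the same direction for Nts and Morn1, pointed the same way without passing for Dipk1b, Olfr10 and Atpaf2 and pointed the opposite way for Erbin. The others, such as Cops6, Cdkn2d and Mmel1, were each called by their only tested probe, with no second probe as a check.

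In total 1632 probes passed between dorsal and ventral, 830 higher and 802 lower in dorsal, with a median size of 1.25 and 190 of over 4-fold; 267 had a region at background on all 3 arrays, and 4548 had an unadjusted p below 0.05. With the mouse as a block there were 1346. Median centring gave 2563 calls, 2159 higher and 404 lower in dorsal. In that setting the median difference of all tested probes was 0.36 for dorsal minus ventral and -0.35 for target minus dorsal. Without dorsal array 2 or 3 the count was 962 or 979. Of 690 genes with a called probe and another tested probe of the same array name, the other probe pointed the same way in 368 (53.3%, exact binomial 95% interval 49.5 to 57.1%, exact binomial p = 0.0866 on both sides against an even share). The median difference was 1.25 for the called probe and 0.03 for the other probe, counted along the direction of the called one. Among the 239 of these genes whose other probe was brighter than a log2 level of 9, that probe pointed the same way in 122 (51.0%, interval 44.5 to 57.5%).

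**Figure D2:**
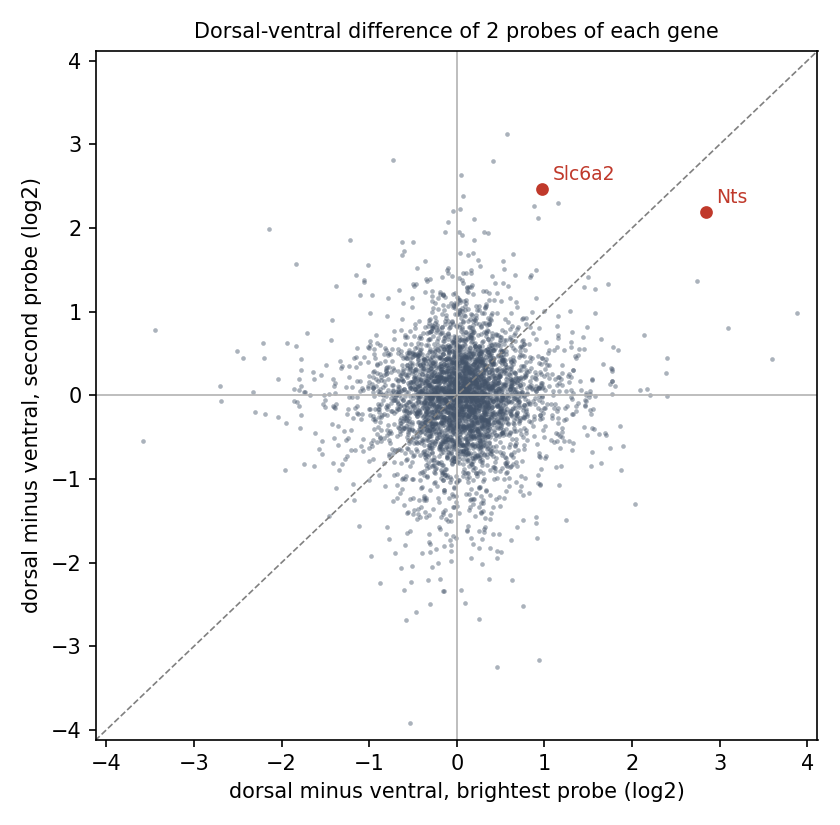
Dorsal minus ventral difference (log2) of the brightest tested probe (horizontal axis) against that of the next brightest tested probe (vertical axis), 1 dot per array name for 3770 names; the dashed line marks equal differences, and Nts and Slc6a2 are in red. The Pearson correlation across names, which are not independent replicates, was 0.05, and both probes of Nts and of Slc6a2 were higher in dorsal.

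Gene groups held called members on both sides between dorsal and ventral, and no list passed by camera (2 had an unadjusted p below 0.05; 0 passed with an estimated correlation and 0 by fry). Of 25 myelin and oligodendrocyte genes 4 were lower in dorsal, 1 was higher and 20 did not pass, with 6 adjusted over the list alone; 15 of the 25 had a positive difference (mean -0.11, median 0.06, camera adjusted p = 0.944). Those lower included Cldn11, which forms the tight junctions of myelin (-1.24, SE 0.17, adjusted p = 0.00338), and Mobp (-1.14, SE 0.19, adjusted p = 0.00707, with 2 of its 4 other probes in the same direction, and not called with median centring). Mbp, the myelin basic protein gene, was lower as well (-0.93, adjusted p = 0.00707, with 4 other Mbp probes not passing and 3 of them pointing the opposite way). The higher one was Septin4 (1.05, adjusted p = 0.00967). Of 12 oligodendrocyte precursor genes 3 were higher and 2 lower, with 5 adjusted over the list alone (camera adjusted p = 0.944). Neu4 (2.39, adjusted p = 1.98e-04, with another probe pointing the opposite way) and the proteoglycan gene Cspg4 (1.0, adjusted p = 0.00839) were among those higher. Bcas1 (-1.29, adjusted p = 0.00440) and the lineage factor gene Sox10 (-1.05, adjusted p = 0.0111) were lower. Cspg4 was also the 1 called gene of 15 mural and meningeal ones (5 adjusted over the list alone, camera adjusted p = 0.974). Laptm5 was lower in dorsal and the only called microglial gene of 15 (-2.59, adjusted p = 0.00164, 1 adjusted over the list alone, camera adjusted p = 0.974). Of 21 pan-neuronal genes Stmn2 (-1.17, adjusted p = 0.0164, with another probe pointing the opposite way) and Eno2 (-0.74, adjusted p = 0.0339) were lower and the neurofilament-type gene Ina higher (1.07, adjusted p = 0.00783), with 4 adjusted over the list alone (camera adjusted p = 0.944). Of 38 potassium and HCN channel genes 3 were higher and none lower, also 3 adjusted over the list alone (camera adjusted p = 0.944). They were the glial inward rectifier genes Kcnj10 (0.85, adjusted p = 0.0168) and Kcnj16 (0.66, adjusted p = 0.0299, 0.0558 with the block), and Kcnab1 (0.61, adjusted p = 0.0463, 0.0795 with the block).

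Transcription factors of the midbrain had 1 higher and 3 lower members of 15, and 4 adjusted over the list alone (camera adjusted p = 0.944). Ebf3 (-1.74, adjusted p = 0.0118, with another probe pointing the opposite way), Tcf7l2 (-1.41, adjusted p = 0.00400) and Ebf1 (at least 1.26-fold, adjusted p = 0.0498, 0.0582 with the block) were lower in dorsal and Nkx2-2 higher (1.33, adjusted p = 0.0144). In the list of thalamus, habenula and pretectum Tcf7l2 was lower and Gbx2 higher (1.30, adjusted p = 0.0301, 0.0625 with the block) among 9 genes, with 2 adjusted over the list alone (camera adjusted p = 0.944). Among transmitter lists Nts was the 1 higher gene of 14 neuropeptides, Prima1 of 4 cholinergic genes (1.50, adjusted p = 0.00627) and Slc6a2 of 7 noradrenergic genes (0.97, adjusted p = 0.0432, 0.0856 with the block; its dimmer probe gave at least 2.53-fold). Maob, a monoamine oxidase gene, was the 1 higher gene of 6 serotonergic ones (0.98, adjusted p = 0.0494, 0.0693 with the block, with 2 of 3 ventral arrays above background and another probe pointing the opposite way). Slc6a5, the neuronal glycine transporter gene, was the 1 lower gene of 6 glycinergic ones (-0.81, adjusted p = 0.0277, 0.0513 with the block; another probe gave -0.14, adjusted p = 0.826). Adjusted over each list alone these 5 counts were 1, 1, 1, 2 and 1, and the camera adjusted p was 0.944 in each. Grik4 was higher among 13 ionotropic glutamate receptors (1.43, adjusted p = 0.00761, 3 adjusted over the list alone, with 2 of 3 ventral arrays above background). So were Rasgrf2 among 8 cortical and hippocampal genes (2.01, adjusted p = 0.0181, 2 adjusted over the list alone, also with 2 of 3) and the activity-regulated gene Arc among 11 immediate early genes (1.26, adjusted p = 0.0104, 1 adjusted over the list alone). Hbb-b1 was higher among 6 blood genes (0.82, adjusted p = 0.0135, 3 adjusted over the list alone, with 5 of its 10 other probes in the same direction and 2 of them called lower, at -1.17 and -0.92). Lower in dorsal were the kinase gene Sgk1 among 20 heat shock and hypoxia genes (-1.92, adjusted p = 0.0164, 1 adjusted over the list alone) and 2 clock genes, Bhlhe40 (-0.86, adjusted p = 0.0121) and Dbp (-0.85, adjusted p = 0.0223, 0.0508 with the block), among 12 circadian genes (3 adjusted over the list alone). The camera adjusted p was 0.702 for blood and circadian genes and 0.944 for the glutamate receptor, cortical, immediate early and heat shock lists.

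In 12 lists no member passed in any comparison. Their camera adjusted p lay between 0.739 and 0.998 for target against dorsal, between 0.793 and 0.904 for target against ventral, and at 0.944 for dorsal against ventral in each. The largest differences were -1.10 for Cckbr, dorsal minus ventral, and at least 1.34-fold more in dorsal than in ventral for the orexin receptor gene Hcrtr2 among 14 neuropeptide and orexin receptors (adjusted p = 0.141 and 0.198). They were 1.84 for Adrb1, target minus dorsal, and 1.27 for Adra2c, dorsal minus ventral, among 19 monoamine, acetylcholine and adenosine receptors (adjusted p = 0.142 and 0.0603). They were 0.85 for Slc10a4, dorsal minus ventral, among 8 dopaminergic genes (adjusted p = 0.317). The next was -0.62 for Neurod1, target minus dorsal, among 4 glutamatergic genes (adjusted p = 0.753). None of 7 GABAergic genes and none of 14 GABA-A and glycine receptor subunits passed. Next came 0.82 for Hpcal1 and -0.81 for Pcp4, dorsal minus ventral, among 9 calcium-binding proteins (adjusted p = 0.215 and 0.0559). Then came 0.88 for Hoxb3, dorsal minus ventral, among 6 hindbrain Hox genes (adjusted p = 0.133, where 1 of its 2 dimmer probes passed). Cerebellar genes gave -1.67 for the Purkinje cell gene Pcp2 and 1.17 for Cbln1, dorsal minus ventral, among 11 (adjusted p = 0.0521 and 0.0889). Markers of other cell types gave 0.56 for Aldh1l1, dorsal minus ventral, among 21 astrocyte genes (adjusted p = 0.0831). They gave 1.16 for Tek, target minus dorsal, and -1.02 for Cldn5, dorsal minus ventral, among 15 endothelial genes (adjusted p = 0.444 and 0.165), and at least 1.50-fold more in dorsal than in ventral for Cox8b among 11 ependymal and choroid plexus genes (adjusted p = 0.190). Not all arrays were above background for Cckbr and Adrb1 (1 of 3 in dorsal), Slc10a4 (2 of 3 in dorsal, 1 of 3 in ventral), Neurod1 (2 of 3 in target), Hpcal1 (1 of 3 in ventral) and Pcp2 (2 of 3 in dorsal). Adjusted over the list alone, 2 of the 19 receptors of monoamines, acetylcholine and adenosine passed for target against dorsal, 1 GABAergic gene for target against ventral, and 1 GABAergic, 1 calcium-binding and 1 cerebellar gene for dorsal against ventral. Over the 32 lists the mean and the median differed in sign in 9 for target against dorsal, 5 for target against ventral and 12 for dorsal against ventral, and the mean and the camera direction in 1, 4 and 6.

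Target was also set against the mean of dorsal and ventral, which a probe can pass without differing from each of them. Nts probe 7320255 (2.03, with 2 of 3 ventral arrays above background), Slc6a2 probe 1070279 (1.96) and Gal (1.57) were among the 14 probes that were higher in target. So were Mark4 (2.77, with 1 of 3) and Trak2 (1.80), which encodes an adaptor that links mitochondria to motor proteins. Nts probe 1850095, Slc6a2 probe 5910717, Calca and Mmel1 also passed, and have no size here since all 3 ventral arrays were at background. Cops6 was the only probe that was lower; it was at background in both target and dorsal and did not pass between them (adjusted p = 0.584). Adjusted p-values of these named probes lay between 0.00316 and 0.0375; the genes were chosen for this list after their values were seen, apart from Nts and Calca. In all 15 probes of 13 genes passed (1652 had an unadjusted p below 0.05), and Nts and Slc6a2 were the 2 genes with more than 1. With the mouse as a block 10 passed: both Nts probes, Slc6a2 probe 5910717, Mark4, Mmel1, Trak2 and Cops6 were kept, while Calca (adjusted p = 0.0694), Gal (0.175) and Slc6a2 probe 1070279 (0.0855) were not. Left-out arrays gave 8 calls without ventral array 1, ventral array 3 or target array 1, and 2 without target array 2 or target array 3.

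Passing against each of dorsal and ventral separately was rarer. Trak2 was higher in target than in dorsal by 2.10 (SE 0.27, adjusted p = 0.0435) and than in ventral by 1.50 (SE 0.27, adjusted p = 0.0329), and was the only probe to do so. Its other 2 tested probes did not pass against dorsal (log2 differences of 0.68 and 0.49, adjusted p = 0.519 and 0.616) or against ventral, where the brightest probe pointed the opposite way (-0.03 and 0.14, adjusted p = 0.973 and 0.856). With the block Trak2 had adjusted p = 0.0511 against dorsal, and a probe of the unnamed locus D130067N01Rik passed in its place (2.27 over dorsal, adjusted p = 0.0451, with 1 of 3 dorsal arrays above background, and adjusted p = 0.00514 over ventral, with none). Leaving out any 1 of the 9 arrays ended the Trak2 call against dorsal (adjusted p from 0.0670 to 0.184). The count was then 0 without dorsal array 1, any ventral array or any target array, and 1, another probe, without dorsal array 2 or 3. No probe was lower in target than in each of the others, by limma with or without the mouse as a block, with trended and robust moderation or with array weights. At an unadjusted p below 0.05 in both, 265 probes lay above or below both on the same side, where 271.9 were found on average when unchanged regions were simulated. The simulated regions had 1 common mean per probe, whereas dorsal and ventral differed at 4548 probes at that unadjusted p. The near equality therefore says nothing on how many probes are particular to target.

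Target and dorsal were both compared with the same ventral arrays. Of the 365 probes called between target and ventral, 326 were also called between dorsal and ventral, and all 326 lay on the same side of ventral. They were 212 higher and 114 lower probes, where independent lists of these sizes would share 9.70 and 4.94. In 20 simulations of unchanged regions no probe was called in both. At most 1 was called there in any pairwise comparison, so that absence says nothing about the overlap. At an unadjusted p below 0.05 in both comparisons there were 2212 probes, 2207 on the same side, where the simulations gave 278.5 and 273 on average. The 3 ventral arrays are too few to be split, so part of the excess may come from sharing them. Among the 1632 probes called between dorsal and ventral the target mean lay between the other means for 1488 (91.2%), against 40.5% of the 18828 other probes whose dorsal and ventral means differed at all; choosing probes for their dorsal-ventral difference by itself favours such a middle place.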

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

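Means over the probes of an array name and counts of names with more than 1 called probe were chosen only after the results were seen; all other settings here were planned. Of 256 values of named genes, 90 passed and 166 did not; none that passed reversed under any alternative, 40 lost the call in at least 1, 28 others gained one, and 31 uncalled values changed sign in at least 1. Nts in target over ventral was called in every alternative that gave it a value (3.16 to 3.60 with 1 array left out, 2.20 to 3.53 otherwise, adjusted p from 1.92e-06 to 0.00464), and in target over dorsal in none (0.55 to 0.64 and 0.17 to 0.63, adjusted p from 0.117 to 0.810). The stricter detection filter removed Nts and gives no value for it. No alternative called a probe lower in target than in each neighbour, or a list between dorsal and ventral. Signal over background limits the rest: dim regions give only bounds, and the cause of the changes below was not tested unless stated.

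Counts for target against dorsal (12), target against ventral (365), target against the mean (15), and higher in target than in each neighbour (1) moved as follows. Without background correction they were 88, 833, 33 and 9, and with the authors' quantile table or series matrix 88, 832, 33 and 9. An offset of 50 gave 46, 557 and 5 for the first, second and last. Median centring gave 178 for target against ventral, 2563 for dorsal against ventral (1632), 9 against the mean and 0 above each neighbour. No filter gave 20 for target against dorsal and 0 above each neighbour; the strict filter, which tests fewer probes, gave 57, 0 against the mean and 2 above each neighbour. Trended and robust moderation gave 125, 832, 36 and 9, and array weights 89 for target against dorsal and 5 above each neighbour. A fit of only the regions compared, which holds fewer arrays, gave 1 for target against dorsal and 123 for target against ventral.

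With the mouse as a fixed block 3 probes passed for target against dorsal and 154 for target against ventral; as a random block (consensus correlation 0.0124) 27 passed for target against dorsal and 3 above each neighbour. The fixed block kept 72 of the 90 named calls. Apart from the 18 given beside their results and the probes of target against the mean, it changed no other call among the 256 named values or the lists. Outside these values, Cdkn2d was lower in target than in ventral (-1.12, limma adjusted p = 0.0352) and lost that call with the block (0.0545). The block for the BeadChip was not run, since chip identifiers are not given in the sources used here.

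Lists passing between target and dorsal (1, noradrenergic neurons) numbered 2 with median centring (cranial motor neurons added, adjusted p = 0.0219), 2 without the filter (the same list added, 0.0480), 2 by fry, 0 with the strict filter and 0 with an estimated correlation. Between target and ventral (0) there was 1 without background correction (blood cells, 0.0465) and 1 in the authors' quantile table or series matrix, 3 with median centring (motor neurons, noradrenergic neurons and blood cells, each 0.0446) and 3 by fry.

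With each array left out in turn, target against dorsal gave 1 to 4 probes, target against ventral 64 to 279, dorsal against ventral 962 to 1432, target against the mean 2 to 15, above each neighbour 0 to 1, and lists between target and dorsal 1 to 3 (3 without dorsal array 3). Of the 90 named calls, 17, 21 and 24 were lost without dorsal arrays 1, 2 and 3, 31, 24 and 21 without ventral arrays 1, 2 and 3, and 20, 22 and 24 without target arrays 1, 2 and 3; a fit of 8 arrays has fewer degrees of freedom.

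Averaged over the tested probes of each of 3770 array names with more than 1, 1 name passed for target against dorsal, 47 for target against ventral and 333 for dorsal against ventral. Names with at least 2 probes called in 1 direction numbered 0, 3 and 27.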

Other observations

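The genes of the first 2 paragraphs, and the tests of second probes, of directions within each mouse, of a shared processing step, of noradrenergic cells and of the background correction, were chosen only after the results were seen. Some genes were called by more than 1 probe of the same array name between dorsal and ventral. Of 46 such names, 27 had all called probes on 1 side. The values below are those of the called probes. Higher in dorsal were Fndc5, the precursor gene of the peptide irisin (1.33 and 2.48, with 2 other probes pointing the opposite way), Vti1a, a gene of vesicle fusion (0.97 and 1.91, with 2 others pointing the same way), Smg6, of nonsense-mediated decay (1.27 and 1.58), and Tns3, a focal adhesion gene (1.29 and 1.45), the last ones with 1 other probe each that pointed the opposite way. Lower in dorsal were Fth1, the ferritin heavy chain gene (-1.28 and -0.76), and Vdac1, the mitochondrial outer membrane channel (-1.16 and -0.65), which had no other tested probe. So were Eif2b5, a translation initiation factor subunit gene (-1.68 and -1.55), and Ptbp1, a splicing regulator (-1.83 and -0.88), with 1 other probe each that pointed the same way. None of these other probes passed. On the ventral side not all arrays were above background for the larger value of Fndc5 (2 of 3) and of Vti1a (1 of 3), both values of Smg6 (2 of 3) and those of Tns3 (2 of 3 and 1 of 3), and on the dorsal side for the larger value of Ptbp1 (1 of 3). The other 19 had called probes on both sides, such as Rap1gap (1.98 and -2.14), Syne1 (2.09 and -1.86, with 3 others not passing) and Cand1 (1.33 and -1.33, with 2 others not passing).

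Averaged over the tested probes that share an array name, 31 names were higher and 16 lower in target than in ventral; probes of the same gene under another array name are left out. Nts (adjusted p = 3.35e-06) and Slc6a2 (adjusted p = 1.11e-05) were among those higher, with no size given since 1 probe of each was at background on all 3 ventral arrays. Also higher were Scn3b, a sodium channel subunit gene (1.24, adjusted p = 0.00992), Bcan, the brevican gene of perineuronal matrix (0.87, adjusted p = 0.0252), and the clock gene Per2 (0.98, adjusted p = 0.0145). Lower were Aldh5a1, which degrades a product of GABA (-0.80, adjusted p = 0.0187), and the transcription factor gene Creb1 (-0.83, adjusted p = 0.0484). Adssl1 was the only one whose mean differed between target and dorsal (1.54, adjusted p = 0.0167). Such a mean can be carried by 1 probe. Between target and ventral only Nts, Slc6a2 and the clone-named 3830406C13Rik had 2 called probes. The Adssl1 mean holds 1 called probe, which alone gave 2.70 between target and dorsal.

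Dorsal and ventral arrays differed at 1632 probes. Different amounts of the whole transcript are argued against as the general cause: the second probe of the same array name pointed the same way for 53.3% of 690 genes (95% limits 49.5 to 57.1%), below a bound of 60% that was set after the share was seen, although genes such as Nts and Slc6a2 moved by both. Sequence variants carried by single mice are argued against by the design alone. By the column names each mouse gave an array to every region, so an effect shared by its arrays cancels from the difference. The difference had the same direction in all 3 mice for 1632 of the 1632 called probes and 7118 of the 18829 others. That decides nothing, since calling a probe selects for such agreement. With the mouse as a block 1246 stayed called. The mouse itself passed for 0 of all tested probes by limma, with 1316 at an unadjusted p below 0.05, which decides nothing either. A processing step shared by the arrays of a region cannot be told apart from region: arrays of a region correlated at a median of 0.944, and the run and chip of each array are not given in the sources used here. Isoforms that differ between regions may also account for it and were not tested, since probe sequences were not used here.

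Nts, Slc6a2, Calca and Gal were all higher in target than in ventral, Calca by probe 6650017 only. Background correction of dim probes is argued against as the cause, since 4 of the 4 were called both without it and in the authors' quantile table. More noradrenergic cells in the target tissue may be a source of Slc6a2 and Gal, which that list holds, and stays open: the other 5 measured genes of the list averaged 0.15 more in target than in ventral, from -0.11 to 0.45 over the 9 pairs of arrays (exact permutation p = 0.4 on both sides, smallest possible 0.1). The 9 pairs cross arrays of different mice as well, and the permutation also leaves the pairing by mouse aside. Dbh and Th, which such cells express strongly, were above background on 0 of the 9 arrays, target included, by 1 probe each, and how well these probes detect them was not tested here; Maoa and Ddc are also expressed outside these cells. A difference between the regions in peptide-expressing neurons is likewise open and was not tested apart from these values.

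The 6 arrays of a pair can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called 12, 365 and 1632 probes for target against dorsal, target against ventral and dorsal against ventral, the highest other split 0, 0 and 1, and 1 of 10 splits reached the real count in each. Of the 10, 4 part all 3 same-mouse pairs, the real one among them, and the others of these called 0 in each comparison. For lists the real split gave 1, 0 and 0 by camera and the highest other 0, so 1, 10 and 10 of the 10 splits reached it.

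Of 840 partitions of the 9 arrays into 3 groups, 100 were drawn, the real one included. For target against the mean of the others 3 of 100 gave at least the real 15 probes; the median of the other partitions was 0. The other two gave 962 and 674, and they set the ventral or the dorsal arrays as the first group, which points to the structure of the regions themselves. For probes above each neighbour 4 of 100 gave at least the real 1 (highest other 67). Both shares are under 0.05. Of the drawn partitions, 10 part all same-mouse pairs, the real one included. Of these, 2 reached the real count in each test (highest other 674 and 3). Beside the real one this was the partition with the dorsal arrays as the first group, and 10 partitions are too few for a share under 0.05. With the pairing kept the test therefore cannot decide, and chance is not excluded. For probes below each neighbour the real count was 0, which all 100 of 100 reach (highest other 169), so chance is not excluded either.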
